A study of Mus musculus with 24 samples.

How the data were processed

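Messenger RNA was measured in bone marrow B cells of 24 irradiated mice on 1-colour Affymetrix mouse gene arrays, with 1 array per mouse. Per the labels, total RNA was extracted with Trizol and the target was labelled with biotin. The deposited values are log2 signals of 35556 probe sets, made by the authors with RMA and the R package oligo, per the submitters' processing notes. RMA subtracts background, normalizes quantiles between arrays and summarizes probes into probe sets on the log2 scale, which compresses differences near background. Versions, filters and batch corrections are not given in the sources used here. The values ran from 3.48 to 14.2, no value was missing, and array medians ran from 6.10 to 6.30. Scanner files were not used here, so background and normalization could be varied only on the deposited values.

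Samples were grouped by the stage and genotype in their labels into leukemic wild type (n = 4), preleukemic wild type (n = 3), preleukemic Pax5+/- (n = 7) and leukemic Pax5+/- (n = 10). The labels call the samples biological replicates and the design text counts mice. All samples, leukemic ones included, carry the label of 3 weeks after irradiation, so the time at which leukemic mice were sampled is not known here. The labels give no batch, scan date or sex. The Y-linked genes Eif2s3y, Kdm5d and Uty were averaged per array, and 12 arrays lay above and 12 below a value of 7 (the nearest values were 8.34 and 4.99).

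Probe sets were named from the platform table, which lists 23410 of them, 21789 with 1 gene symbol and 1621 with several. The remaining 12146 probe sets are unnamed here. Probe sets with several symbols or none named no gene. The 19938 named genes took the probe set with the highest mean where a gene had several, as 999 did. A gene was tested when its value reached the 30th percentile of the array (5.18 to 5.35) on at least 3 arrays, which left 15647 genes and set aside 4291. This percentile is called the dim level, and no detection calls were available. Where a named gene lay at or below it on arrays of its lower group, each of those arrays was set to its dim level and the fold is given as at least that value. No genome was used, and the RefSeq gene table of GRCm38.p6 served only for names and for the order of neighbouring genes.

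The comparisons numbered 5: leukemic with preleukemic samples within each genotype, the difference of these differences, and Pax5+/- with wild type within each stage. Means of the 4 groups were fitted to all 24 arrays with limma 3.58.1 (lmFit, contrasts.fit and eBayes; 20 residual and 2.29 prior degrees of freedom) in R 4.3.3. Tests were two-sided with Benjamini-Hochberg adjustment over the genes tested, and genes were called at an adjusted p under 0.05. Pax5 was also compared by exact permutation of the arrays, adjusted over 4 comparisons. Gene lists numbered 33 with 641 genes, of which 550 were tested. They covered B-lineage stages, Pax5 targets, other marrow cell types, DNA repair, p53 targets, the cell cycle, metabolism and signalling. No gene of the mitochondrially encoded list was tested, so 32 lists were analysed. Lists were tested with camera at a preset correlation between genes of 0.01, with an estimated correlation and with fry as alternatives. Independent lists were taken to share n1 × n2 / N genes.

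The groups, tests, gene lists, alternatives and the rule for named genes were fixed before the data were examined. The rule took Pax5 in every comparison, the 10 called genes with the largest rise and the 10 with the largest fall whose groups do not overlap in each stage comparison, up to 4 called members of each list in each stage comparison (where no member was called, the 2 with the smallest p), and the 10 called genes with the largest absolute difference in the other comparisons. It left out antigen receptor segments, predicted genes and small RNAs. A fixed panel of genes of B-cell leukemia was added, some of which were not analysed here.

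The fit was tested on simulated arrays of the same 15647 genes. These gave all groups the same SD per gene with independent normal noise, and changed only a small set of genes. Changes of 1 on the log2 scale were recovered in 98.6% of cases for the Pax5+/- stage comparison, 91.3% for the wild-type stage comparison, 75% for the difference between them, 91.2% for the leukemic and 85.5% for the preleukemic genotype comparison. Changes of 0.5 were recovered in 72.1%, 40.8%, 39.7%, 74.6% and 63.4%, and false calls made up 3.7%, 3.8%, 5.4%, 7.3% and 5.8% of calls. In the data the median SD of a gene ran from 0.123 to 0.17 between groups, and up to 9839 genes were called. The simulated rates therefore need not hold there. Duplicate arrays were checked through correlations and root mean square differences between all pairs of arrays, and the lowest such difference was 0.179.

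Alternatives were a trended and robust eBayes, a fit of only the groups compared, array weights by group, no filter or a stricter filter at the 50th percentile, all probe sets, the mean of a gene's probe sets, repeated quantile normalization, arrays centred on their medians, the replicate number as a block, and each array left out in turn. Alternatives chosen after the data were seen were the Y-linked mean or the granulocyte mean as a covariate, arrays with high or low Y-linked values alone, and the Y-linked covariate without preleukemic wild-type array 1. Figures were drawn with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.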

Results

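The series measured messenger RNA in bone marrow B cells of irradiated mice on 24 arrays. Every mouse had received 2 Gy of ionizing radiation. Leukemic samples came from tumor-bearing marrow of 10 mice with 1 functional Pax5 allele (Pax5+/-) and of 4 wild-type mice. Preleukemic samples were pro-B and pre-B cells of 7 Pax5+/- and 3 wild-type mice, taken 3 weeks after irradiation. Pax5 encodes the transcription factor that commits lymphoid progenitors to the B lineage, and the study asked how its reduced activity acts in radiation-induced B-cell leukemia. The stages differ in cell material as well as in disease, because the leukemic samples are described as tumor-bearing marrow and the preleukemic samples as pro-B and pre-B cells. The values were deposited log2 signals, and 15647 named genes were tested. Array medians over all probe sets ran from 6.104 to 6.219 in leukemic and from 6.226 to 6.296 in preleukemic arrays. They did not overlap, so the array median goes with stage. The number of arrays limits the precision of every value, most of all in the preleukemic wild-type group.

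Leukemic and preleukemic arrays lay apart on the first principal component, which held 59.1% of the variance. Preleukemic wild-type array 1 stood apart from its group. Its component value was -17.8, against -50.8 and -56.1 in the other 2 arrays. Its mean over the granulocyte genes was 10.28, against 6.44 and 6.48, and its mean over the mitosis genes was 9.70, against 7.74 and 7.92. The sexes of the mice were not given in the labels. Y-linked genes were high in all 3 preleukemic wild-type arrays and low in all 4 leukemic wild-type arrays, so sex and stage cannot be told apart within the wild type by design. High and low arrays numbered 4 and 3 in preleukemic Pax5+/- and 5 and 5 in leukemic Pax5+/- samples. No arrays were identical, and the highest correlation between any pair was 0.995. The median SD of a gene was 0.133 in leukemic wild-type, 0.151 in preleukemic wild-type, 0.123 in preleukemic Pax5+/- and 0.17 in leukemic Pax5+/- arrays.

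**Figure D1:**
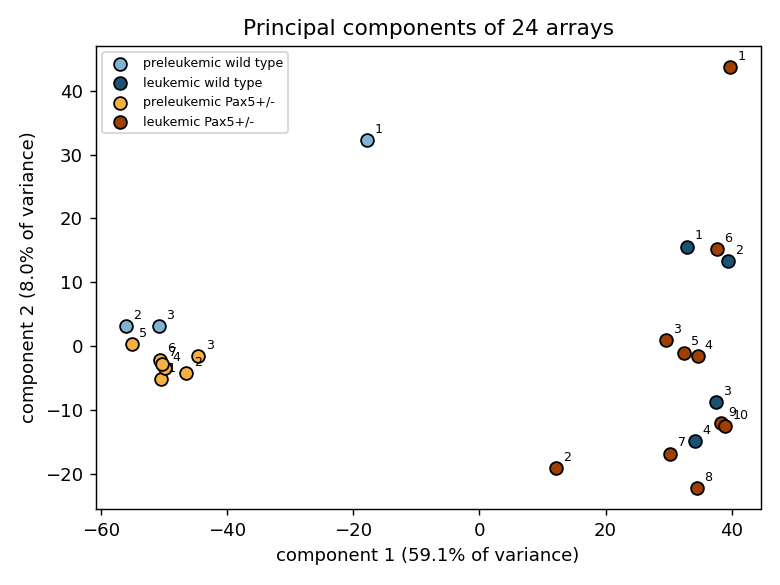
Principal components of the 24 arrays, with component 1 (59.1% of the variance) on the x axis and component 2 (8% of the variance) on the y axis. Each point is an array numbered by its replicate, and preleukemic wild-type array 1 lies at -17.8 on component 1, away from the other 2 arrays of its group.

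Pax5 was on average lower in leukemic than in preleukemic samples of both genotypes. In Pax5+/- mice it averaged 11.43 ± 0.09 (SD, n = 7) before leukemia and 8.53 ± 1.22 (SD, n = 10) in leukemia, a log2 difference of -2.90 (two-sided exact permutation p = 0.000206, adjusted p = 0.000824 over 4 comparisons). In leukemic Pax5+/- array 2 Pax5 was 11.37, within the preleukemic range of 11.34 to 11.59, and it ran from 6.87 to 9.38 in the other leukemic Pax5+/- arrays. In wild-type mice it averaged 11.88 ± 0.36 (SD, n = 3) and 9.45 ± 2.10 (SD, n = 4), a log2 difference of -2.43. The exact permutation test gave p = 0.0857 (adjusted p = 0.114) for the wild type, and limma gave an adjusted p of 0.0256. Leukemic wild-type array 2 had a Pax5 value of 6.34, and without it the difference was -1.39 (adjusted p = 0.106). The wild-type call also ended without preleukemic array 2 (-2.37, adjusted p = 0.0752) and without preleukemic array 3 (-2.29, adjusted p = 0.0859). Between genotypes Pax5 differed by -0.45 in preleukemic samples (exact p = 0.0333, adjusted p = 0.0666) and by -0.92 in leukemic samples (exact p = 0.311, adjusted p = 0.311), neither past the threshold after adjustment. The stage differences of Pax5 did not differ detectably between genotypes (-0.47 ± 1.00 (SE), limma adjusted p = 0.956). Both of the latter values rest on leukemic wild-type array 2: without it the leukemic genotypes differed by -1.95 (limma adjusted p = 0.419) and the stage differences by -1.51 (adjusted p = 0.697). The labels do not say whether the Pax5 probe set covers the part of the gene changed in Pax5+/- mice. Its signal need not measure functional Pax5, so the genotype differences cannot decide whether the mutation lowered it.

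**Figure D2:**
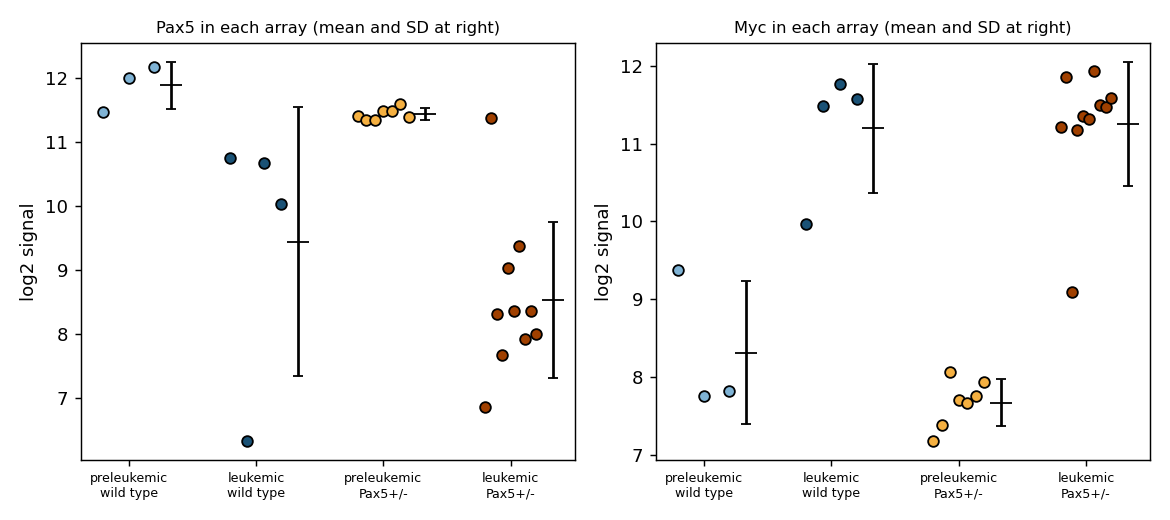
Log2 signal of Pax5 (left) and Myc (right) in each array, by group, with the group mean and SD at the right of each group. Pax5 averaged 11.43 in preleukemic and 8.53 in leukemic Pax5+/- arrays, and Myc rose by 3.58 on the log2 scale between these groups.

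The comparison of leukemic with preleukemic Pax5+/- samples asked which transcripts changed when leukemia arose in the susceptible genotype. Lists of Pax5-activated, pro-B and pre-B, mature B-cell and immediate-early genes were lower, and lists of mitosis, DNA replication, ribosome biogenesis, granulocyte, monocyte, platelet and stromal genes higher. These lists passed with a preset correlation between genes, and none did with an estimated correlation (adjusted p from 0.291 to 0.655). Myc, an oncogene that drives growth and ribosome synthesis, was 11.9-fold higher (log2 difference 3.58 ± 0.33 (SE), adjusted p = 7.23e-09). Fcrla, an Fc receptor-like protein of B cells, was 45.2-fold lower (-5.50 ± 0.15, adjusted p = 1.7e-17). Of 15647 genes, 4354 rose and 5485 fell (62.9% called, limma with Benjamini-Hochberg adjustment), and of these 1053 rose and 468 fell at least 2-fold. With each array centred on its median the split was 2827 higher and 8930 lower, since centring moved the median of all genes by -0.20 (log2). Directions given below held under centring and repeated quantile normalization unless stated.

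Genes that Pax5 activates fell together: 19 of 23 fell, 1 rose and 3 were not called (adjusted p = 2.31e-07; 0.291 as adjusted p with an estimated correlation). Ikzf3, a transcription factor of differentiating B cells, was 31.5-fold lower, and Cd72, a B-cell surface receptor, was 13.7-fold lower. Of 24 pro-B and pre-B genes 14 fell and 3 rose (adjusted p = 0.01; adjusted p = 0.513 with an estimated correlation). Both recombinase genes that cut antigen receptor loci fell, Rag1 5.92-fold and Rag2, at or below the dim level on 1 of 10 leukemic arrays, at least 6.78-fold. Lef1, a transcription factor of pro-B cells, was 8.68-fold lower, whereas Kit, the stem cell factor receptor, was 3.91-fold higher. Ebf1, which specifies the B lineage with Pax5, was 2.93-fold lower and Ikzf1, which encodes Ikaros, 1.55-fold lower. Among 21 mature B-cell genes 9 fell and 1, Cxcr5, rose by 1.85 (adjusted p = 0.033; adjusted p = 0.513 with an estimated correlation). Genes of pre-B-cell receptor signalling did not pass as a group (9 of 18 fell and 3 rose, adjusted p = 0.11), although the kinase gene Syk was 3.62-fold lower. Plasma-cell genes also did not pass (7 of 14 fell and 3 rose, adjusted p = 0.204). In that list Irf4 fell by 2.92 and Jchain, which links immunoglobulin subunits into polymers, rose by at least 4.97 (at or below the dim level on 6 of 7 preleukemic arrays).

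Genes that Pax5 represses were higher as a group: 10 of 21 rose and 4 fell (adjusted p = 0.0267; adjusted p = 0.547 with an estimated correlation). The receptor tyrosine kinase gene Flt3, active in early lymphoid progenitors, was 29.8-fold higher, and Emb, at or below the dim level on 2 of 7 preleukemic arrays, at least 28.2-fold higher. Members of this list stand in lists of other cells too: Csf1r (which rose by 2.41) and Ccr2 (0.71, not called) in the monocyte and macrophage list, of which 13 of 16 rose (adjusted p = 3.95e-05; adjusted p = 0.513 with an estimated correlation), and Flt3 in the dendritic-cell and stem and progenitor lists. Cd44 and Sdc1 in the Pax5-repressed list were 2.93-fold and 2.5-fold lower. Of 14 stem and progenitor genes 5 rose and 3 fell, without passing as a group (adjusted p = 0.11), and Lmo2 was 5.79-fold higher.

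The proliferation lists moved upward. All 24 mitosis genes rose (adjusted p = 2.98e-08; adjusted p = 0.513 with an estimated correlation), among them the mitotic kinase gene Plk1 (3.86-fold) and the kinesin gene Kif20a (3.00-fold). Of 27 DNA replication genes 20 rose and 1, Pcna, fell by 0.23 (adjusted p = 0.000149; adjusted p = 0.547 with an estimated correlation), and Tyms, which makes thymidylate, was 3.15-fold higher. Of 20 MYC target and ribosome biogenesis genes 19 rose (adjusted p = 1.27e-09; adjusted p = 0.513 with an estimated correlation), led by the spermidine synthase gene Srm (5.83-fold). Of 15 glycolysis genes 10 rose and 1 fell (adjusted p = 0.000396; adjusted p = 0.513 with an estimated correlation), with Ldha 2.58-fold and the glucose transporter gene Slc2a3 5.73-fold higher. Ribosomal protein genes were higher in the deposited scaling (12 of 19 rose and 1 fell, adjusted p = 0.00117; adjusted p = 0.513 with an estimated correlation), but with centred arrays 5 rose and 6 fell. Immediate-early and heat-shock genes fell (13 of 18, none rose, adjusted p = 0.00238; adjusted p = 0.547 with an estimated correlation), with the AP-1 subunit genes Fosb 7.21-fold and Jund 6.38-fold lower. The groups overlapped in the mean of this list. It was 7.64 and 7.51 in preleukemic Pax5+/- arrays 1 and 4, within the leukemic range of 7.07 to 7.83. In the remaining preleukemic Pax5+/- arrays it ran from 8.50 to 8.82.

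Repair genes moved in a mixed way. DNA-damage sensing and checkpoint genes were higher (17 of 22 rose and 3 fell, adjusted p = 0.000179; adjusted p = 0.513 with an estimated correlation). In that list Nbn was 1.89-fold and Tipin 1.91-fold higher, and Rad9a was 1.72-fold lower. Atm, the kinase that signals double-strand breaks, was 1.64-fold higher. Homologous recombination and Fanconi genes were also higher (17 of 25 rose and 5 fell, adjusted p = 0.00554; adjusted p = 0.549 with an estimated correlation), with Fancd2 2.36-fold higher and Rad52 1.76-fold lower. Non-homologous end-joining genes divided, 7 higher and 8 lower of 16 (adjusted p = 0.951). Within that list the polymerase gene Polm was 18.5-fold and the ligase gene Lig4 4.75-fold lower, while Xrcc5, which encodes Ku80, was 3.25-fold higher. Base-excision repair genes did not pass as a group (9 of 18 rose and 5 fell, 5 and 5 with centred arrays, adjusted p = 0.238). There the glycosylase gene Neil1 was 11.7-fold lower and the endonuclease gene Apex1 3.74-fold higher. Mismatch and nucleotide-excision repair genes divided as well (7 of 20 rose and 9 fell, adjusted p = 0.951), with Ddb2 2.15-fold higher and Msh3 2.36-fold lower. Of 26 p53 target genes 5 rose and 7 fell, 2 and 12 with centred arrays (adjusted p = 0.57), and Btg2 was 8.78-fold and Rrm2b 6.78-fold lower.

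Markers of other marrow cells rose beside these groups. All 9 megakaryocyte and platelet genes rose (adjusted p = 4.08e-05; adjusted p = 0.513 with an estimated correlation), and the platelet chemokine gene Ppbp was 72.3-fold higher (6.18 ± 0.29 (SE)). Of 14 stromal and endothelial genes 11 rose and 1 fell (adjusted p = 0.000111; adjusted p = 0.513 with an estimated correlation), with the matrix protein gene Sparc 15.3-fold higher. Of 16 monocyte and macrophage genes 13 rose (adjusted p = 3.95e-05; adjusted p = 0.513 with an estimated correlation), among them the complement gene C1qb (9.12-fold). Of 20 granulocyte genes 11 rose (adjusted p = 0.007; adjusted p = 0.655 with an estimated correlation), with Mmp9 9.56-fold higher. The granulocyte mean ran from 6.06 to 10.31 across the leukemic Pax5+/- arrays and from 6.07 to 6.67 across the preleukemic ones. T-cell genes (5 of 17 rose and 1 fell, adjusted p = 0.204), dendritic-cell genes (6 of 14 rose and 1 fell, adjusted p = 0.221), erythroid genes (1 of 12 rose and 1 fell, adjusted p = 0.991) and NK-cell genes (1 of 12 rose, adjusted p = 0.889) did not pass.

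IL-7 and JAK-STAT genes divided (3 of 18 rose and 5 fell, adjusted p = 0.951), and Il7r, Jak1, Cdkn2a and Dntt were not called, with log2 differences of -0.32, 0.26, -0.02 and 0.58. BCL2 family genes divided too (6 of 14 rose and 4 fell, 4 and 7 with centred arrays, adjusted p = 0.991), with the survival gene Bcl2 6.28-fold higher and Bcl2l1, which encodes Bcl-xL, 4.78-fold lower. Leukaemia oncogenes and tumour suppressors (8 of 27 rose and 13 fell, adjusted p = 0.254), type I interferon response genes (7 of 18 rose, adjusted p = 0.058) and NF-kB response genes (2 of 13 rose and 7 fell, adjusted p = 0.204) stayed above the threshold. The interferon list passed without leukemic Pax5+/- array 2 (adjusted p = 0.0243), 8 (0.0473), 9 (0.0324) or 10 (0.0498). Adjusted over the list alone, the counts were 18 higher for homologous recombination and Fanconi genes, 14 lower for immediate-early and heat-shock genes, 5 higher for dendritic-cell genes, 6 higher for interferon genes and 1 lower alone for erythroid genes, and the same as above for the other 27 lists. None of the 16 lists that passed with a preset correlation between genes held with an estimated correlation, and fry, which tests whether a list moves one way without reference to other genes, called 23 lists. The median and the mean or the test differed in sign for 6 lists that did not pass, those of NK-cell, erythroid, mismatch and nucleotide-excision repair, p53 target, IL-7 and JAK-STAT and BCL2 family genes.

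**Figure D3:**
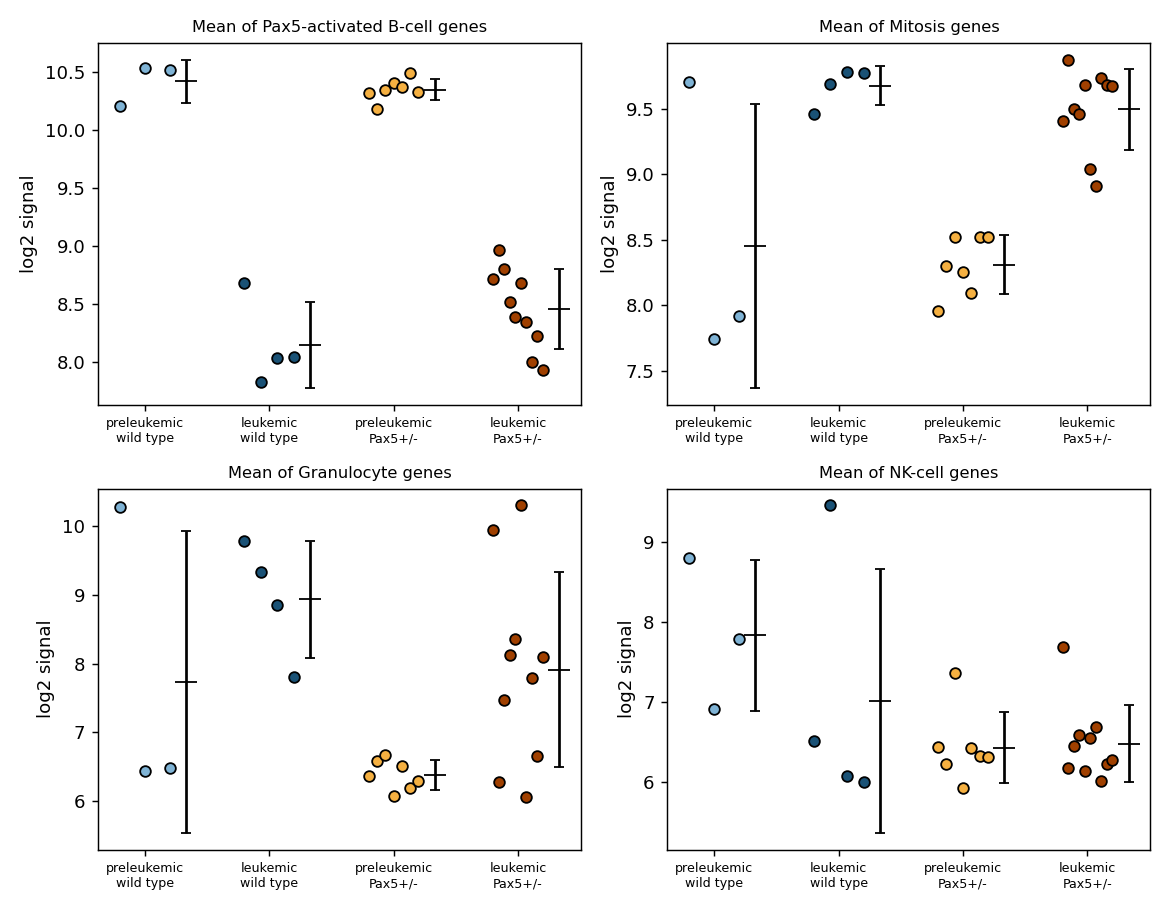
Mean log2 signal over the tested genes of selected gene lists in each array, by group. Granulocyte means ran from 6.06 to 10.31 across leukemic Pax5+/- arrays, and preleukemic wild-type array 1 reached 10.28.

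The comparison of leukemic with preleukemic wild-type samples asked the same of leukemias that arose without the inherited Pax5 mutation. Lists of Pax5-activated, pro-B and pre-B and mature B-cell genes were lower and lists of mitosis, DNA replication, MYC target and platelet genes higher. Of the 17 lists that passed, none did with an estimated correlation (adjusted p from 0.0819 to 0.575). Ppbp was 96-fold higher (6.58 ± 0.45 (SE), adjusted p = 4.21e-10), Myc 7.37-fold higher (adjusted p = 0.00015) and Fcrla 34.9-fold lower (adjusted p = 6.03e-13). Of 15647 genes 2924 rose and 3191 fell (39.1% called), and of these 883 rose and 560 fell at least 2-fold. Centred arrays gave 2214 higher and 5741 lower, with the median of all genes moved by -0.12 (log2). Without preleukemic array 3, 2048 genes fell, and without preleukemic array 1, 7047 genes were called, of which 5673 were shared with the full set in the same direction.

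Of 23 Pax5-activated genes 19 fell and none rose (adjusted p = 2.6e-10; adjusted p = 0.0819 with an estimated correlation), with Siglecg 23.4-fold and Ikzf3 25.6-fold lower. Pro-B and pre-B genes fell (13 of 24, with 2 higher, adjusted p = 0.000171; adjusted p = 0.26 with an estimated correlation), with Rag1 11.1-fold lower (7.23-fold without leukemic array 2) and Rag2, at or below the dim level on 1 of 4 leukemic arrays, at least 9.01-fold lower. Genes of pre-B-cell receptor signalling fell (9 of 18, with 2 higher, adjusted p = 0.00401; adjusted p = 0.26 with an estimated correlation), and the adaptor gene Blnk was 9.87-fold lower (6.19-fold without leukemic array 2 and 15.3-fold without leukemic array 3). Mature B-cell genes fell (9 of 21, adjusted p = 0.00123; adjusted p = 0.26 with an estimated correlation), with the IgM Fc receptor gene Fcmr 18.1-fold lower. Immediate-early and heat-shock genes were lower (5 of 18 fell, adjusted p = 0.0129; adjusted p = 0.575 with an estimated correlation), although without preleukemic array 2 the adjusted p was 0.237. NF-kB response genes were lower (7 of 13 fell and 1 rose, adjusted p = 0.0309; adjusted p = 0.575 with an estimated correlation), with Nfkbie 3.99-fold lower and Tnf 3.32-fold higher. That call ended without preleukemic array 1 (adjusted p = 0.0577).

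Mitosis genes rose (22 of 24, adjusted p = 1.23e-08; adjusted p = 0.374 with an estimated correlation), as did DNA replication genes (23 of 27, adjusted p = 8.13e-11; adjusted p = 0.26 with an estimated correlation) and MYC target and ribosome biogenesis genes (19 of 20, adjusted p = 1.59e-12; adjusted p = 0.26 with an estimated correlation). Plk1 was 3.76-fold, Pole 2.95-fold and Srm 6.52-fold higher. The mitosis mean of preleukemic array 1 was 9.70, within the leukemic range of 9.46 to 9.78, and the Plk1 rise was 6.82-fold without that array and 2.5-fold without preleukemic array 2. DNA-damage sensing and checkpoint genes rose (16 of 22, with 1 lower, adjusted p = 6.59e-06; adjusted p = 0.26 with an estimated correlation), led by the checkpoint kinase gene Chek1 (3.19-fold). Homologous recombination and Fanconi genes rose (15 of 25, with 4 lower, adjusted p = 0.000275; adjusted p = 0.427 with an estimated correlation), including Brca2 (2.37-fold). Glycolysis genes (7 of 15 higher, adjusted p = 0.0007) and ribosomal protein genes (12 of 19 higher, 5 with centred arrays, adjusted p = 1.62e-05) rose as well, both with an adjusted p of 0.26 with an estimated correlation. Neil1 was 10.5-fold, Lig4 4.69-fold and Polm 18.8-fold lower, and Xrcc5 was 3.64-fold higher.

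Among markers of other cells, all 9 megakaryocyte and platelet genes rose (adjusted p = 1.8e-06; adjusted p = 0.26 with an estimated correlation), and 11 of 14 stromal and endothelial genes rose with 1 lower (adjusted p = 1.3e-05; adjusted p = 0.26 with an estimated correlation). Monocyte and macrophage genes rose (8 of 16, adjusted p = 0.00014; adjusted p = 0.374 with an estimated correlation), with Vcam1 10.9-fold higher. Erythroid genes rose (6 of 12, adjusted p = 0.00401; adjusted p = 0.512 with an estimated correlation); their mean was 9.44 and 9.17 in leukemic arrays 1 and 2 and 6.96 and 7.62 in arrays 3 and 4. Granulocyte genes did not pass (adjusted p = 0.0518), but did without leukemic array 4 (0.00975) or preleukemic array 1 (adjusted p = 0.000121), and without leukemic array 3 the value lay just under the threshold (adjusted p rounded to 0.05). NK-cell genes did not pass (adjusted p = 0.389) except without leukemic array 2 (adjusted p = 0.00298), whose NK-cell mean was 9.46. Xist, expressed from the inactive X chromosome, was at least 108-fold higher (at or below the dim level on 2 of 3 preleukemic arrays), and the Y-linked Eif2s3y at least 15.7-fold lower (on all 4 leukemic arrays). Xist lost its call without preleukemic array 3 (adjusted p = 0.0527), and Eif2s3y without preleukemic array 2 (0.0625) or 3 (adjusted p = 0.0619). None of the 17 lists called here held with an estimated correlation, and fry called 21. Pax5-repressed genes did not pass (7 of 21 rose and 3 fell, adjusted p = 0.0674), but did without leukemic array 4 (0.03) or preleukemic array 1 (adjusted p = 0.00844). Adjusted over the list alone, 21 Pax5-activated, 15 pro-B and pre-B and 10 pre-B-cell receptor signalling genes were lower. On the same terms 24 mitosis, 24 DNA replication, 20 MYC target, 18 DNA-damage sensing (2 lower), 18 homologous recombination, 15 ribosomal protein and 7 erythroid genes were higher, and the other lists of these paragraphs kept their counts.

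**Figure D4:**
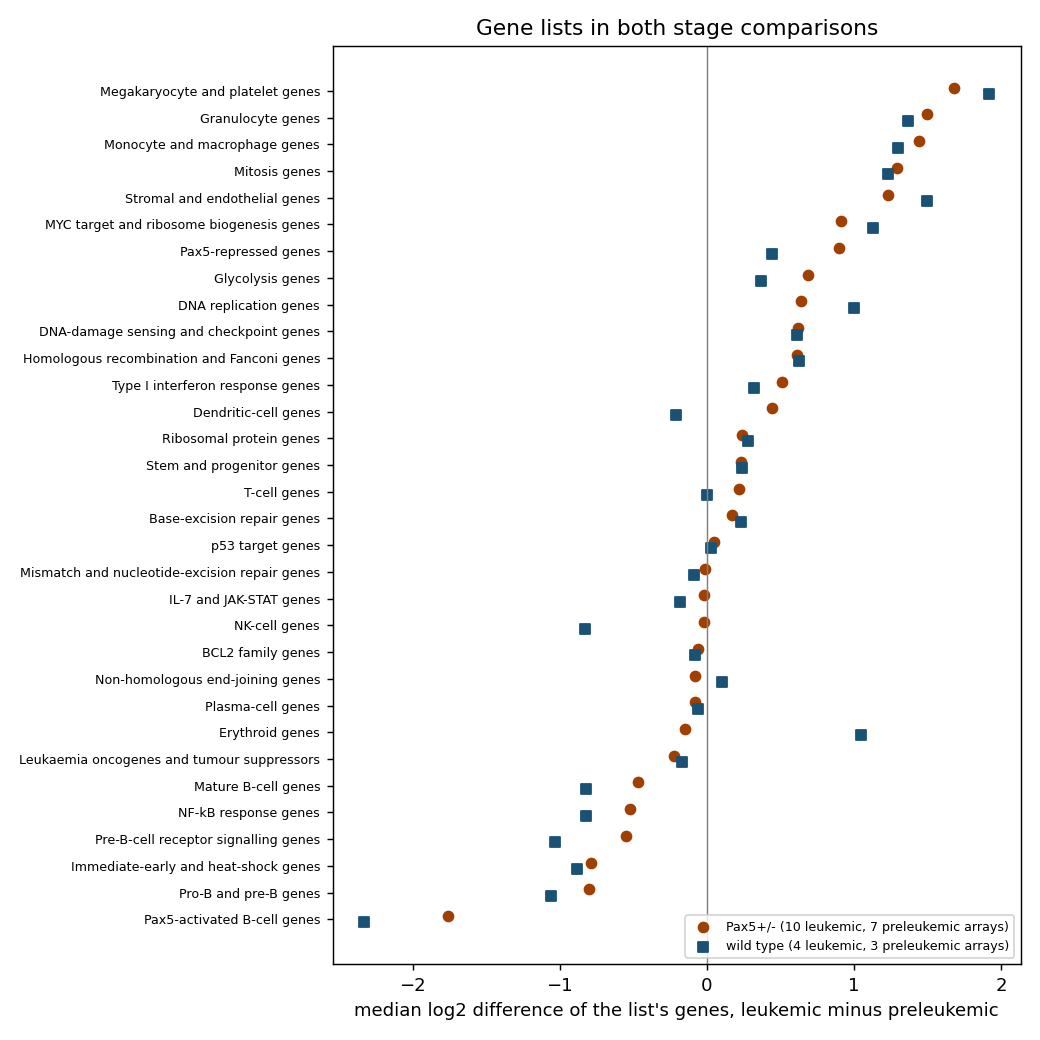
Median log2 difference of each gene list between leukemic and preleukemic samples, for Pax5+/- and wild-type mice. Test outcomes are not marked. Pax5-activated genes had medians of -1.76 and -2.33 and mitosis genes of 1.29 and 1.23, and with centred arrays ribosomal protein genes had medians of 0.04 and 0.16, with 5 rises and 6 falls in Pax5+/- mice.

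The stage changes of the genotypes largely coincided. Among the called genes, 2652 rose in both, against 814 for independent lists, and 2805 fell in both, against 1119. Only 10 genes were called in opposite directions, against 1913, and the log2 differences correlated across the 15647 genes at Pearson's r = 0.90 and Spearman's rho = 0.86, though genes are not independent replicates. These comparisons share no arrays, but their tests share 1 estimate of the spread per gene, so the counts for independent lists are only a reference. Both also set tumor-bearing marrow against pro-B and pre-B cells. How much of the overlap comes from that difference in cell material was not tested. Ppbp, Sparc, Jchain and Mrgpra1 were among the strongest rises, and Fcrla, Cpm, Reln, Polm, Ikzf3 and Atp1b1 among the strongest falls, in both genotypes.

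**Figure D5:**
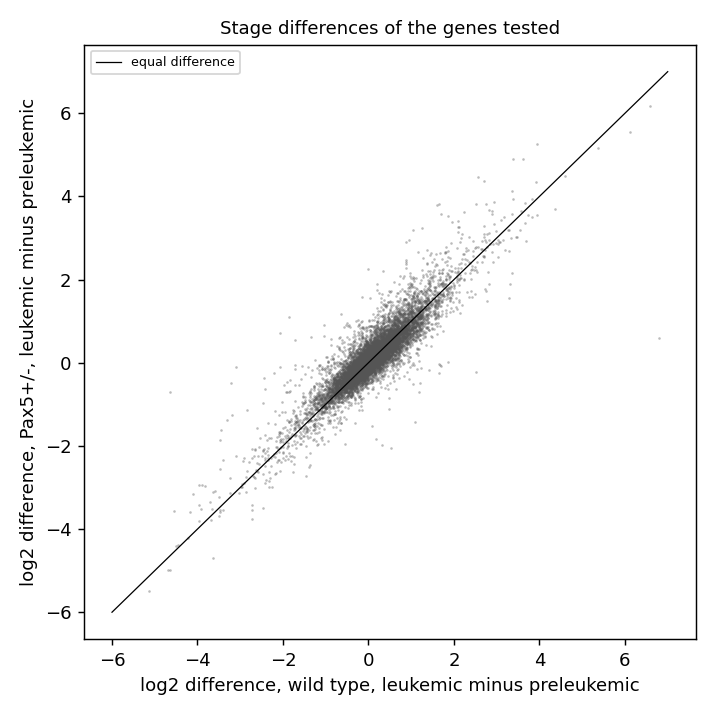
Log2 difference between leukemic and preleukemic samples for each tested gene, wild type on the x axis and Pax5+/- on the y axis, with a line of equal difference. The 15647 genes correlated at 0.90, and 10 were called in opposite directions.

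The difference between these stage changes was tested directly, and few genes passed. In 28 genes the change was more positive in Pax5+/- mice and in 1, Oaf (-1.14), more negative; Oaf was chosen after its values were seen. With centred arrays these counts were 22 and 6, and with quantile normalization repeated 23 and 4. Dock9, a guanine nucleotide exchange factor, fell by 2.07 in wild-type mice and rose by 0.72 in Pax5+/- mice (interaction 2.79 ± 0.38 (SE), adjusted p = 0.000933). The difference was also positive for Edaradd (1.95, adjusted p = 0.000246) and the glutamine transporter gene Slc1a5 (1.95, adjusted p = 0.00358). Slc1a5 averaged 11.68 in preleukemic and 9.62 in leukemic wild-type samples, and 8.53 and 8.42 in Pax5+/- samples. Edaradd averaged 9.22 and 6.02 in wild-type samples, and 7.26 and 6.01 in Pax5+/- samples. Its value thus restates the difference between preleukemic genotypes (-1.97). Of these 29 genes 28 were also called between the preleukemic genotypes, a comparison that shares its 10 arrays with this one and forms part of it. Without preleukemic wild-type array 3 the count of more positive genes was 10, and without leukemic wild-type array 4 it was 18; the count of more negative genes ran from 0 without leukemic wild-type array 4 (447 by limma at an unadjusted p < 0.05) to 9 without preleukemic wild-type array 1. The change of Pax5-activated genes did not pass as different between genotypes (adjusted p = 0.0774; adjusted p = 0.774 with an estimated correlation), but did without leukemic wild-type array 1 (0.00518) or leukemic Pax5+/- array 8 (0.0367), 9 (0.0434) or 10 (adjusted p = 0.0283).

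Leukemic Pax5+/- and leukemic wild-type samples were set against each other to compare the leukemias, and erythroid transcripts were high in part of the wild-type arrays. The mean of erythroid genes was 9.44 and 9.17 in leukemic wild-type arrays 1 and 2, 6.96 and 7.62 in arrays 3 and 4, and from 6.19 to 6.93 in leukemic Pax5+/- arrays. Of 12 erythroid genes 4 were lower in Pax5+/- leukemia, and 11 adjusted over the list alone (adjusted p = 5.37e-24, and adjusted p = 0.0271 with an estimated correlation). The carbonic anhydrase gene Car1 was 9.94-fold lower (-3.31 ± 0.58 (SE), adjusted p = 0.0221), and Slc4a1, the band 3 anion exchanger of red cells, 7.26-fold lower (adjusted p = 0.045). Ly86, which encodes MD-1, was 4.47-fold higher (2.16 ± 0.25, adjusted p = 0.000173) and Gnb4 3.15-fold higher (adjusted p = 0.00902). In all 8 genes were higher and 17 lower, and 6 and 27 with centred arrays; 8 of 100 splits of these arrays called as many or more. Without leukemic wild-type array 2 the counts were 1 and 0 by limma (792 genes at an unadjusted p < 0.05, where chance alone gives 782), with Car1, Slc4a1 and Gnb4 at adjusted p values of 0.195, 0.286 and 0.0763; without array 1 Car1 and Slc4a1 stood at 0.0684 and 0.126 with counts of 15 and 8, without array 3 the counts were 23 and 110, with Car1 15.2-fold and Slc4a1 12.6-fold lower, and without array 4 they were 4 and 45. Without any of leukemic Pax5+/- arrays 2, 3, 4, 6 or 7 the counts were 3 to 4 higher and 3 to 11 lower, and without array 5, 5 genes were lower. Slc4a1 also lost its call without any of leukemic Pax5+/- arrays 1 to 9 (adjusted p from 0.0504 to 0.0669).

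Other lists passed between the leukemic genotypes only with a preset correlation. Granulocyte genes were lower in Pax5+/- leukemia (adjusted p = 2.94e-05; adjusted p = 0.872 with an estimated correlation), and pre-B-cell receptor signalling genes were higher (adjusted p = 0.00206; adjusted p = 0.58 with an estimated correlation), with 3 of 18 higher adjusted over the list alone. Pax5-activated genes were higher (adjusted p = 0.00403; adjusted p = 0.716 with an estimated correlation), as were pro-B and pre-B genes (adjusted p = 0.00175; adjusted p = 0.716 with an estimated correlation). Mitosis, DNA replication and MYC target genes were lower (adjusted p = 0.0134, 0.00242 and 0.00403), each with adjusted p = 0.872 with an estimated correlation. The mitosis call ended without leukemic wild-type array 3 (0.13) or leukemic Pax5+/- array 6 (0.0604) or 7 (0.107), the DNA replication call without Pax5+/- array 7 (0.0577), and the MYC call without wild-type array 3 (0.24) or Pax5+/- array 3 (adjusted p = 0.0619). Without leukemic wild-type array 2 the Pax5-activated, pro-B and pre-B, and pre-B-cell receptor lists gave adjusted p values of 0.0532, 0.174 and 0.0517. Mature B-cell genes were higher (adjusted p = 0.042; adjusted p = 0.754 with an estimated correlation) and NK-cell genes lower (adjusted p = 0.0465; adjusted p = 0.872 with an estimated correlation). The mature B-cell call ended without leukemic wild-type array 1 (0.0725), 3 (0.0691) or 4 (0.166) or leukemic Pax5+/- array 1 (0.126), 4 (0.057), 7 (0.056) or 9 (adjusted p = 0.0715). The NK-cell genes turned in direction without leukemic wild-type array 2 (0.119), and the call ended without leukemic Pax5+/- array 2 (0.0662), 5 (0.0629), 7 (0.0545), 8 (0.119), 9 (0.0788) or 10 (adjusted p = 0.096).

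Preleukemic Pax5+/- and wild-type cells differed in 123 genes, 41 higher and 82 lower in Pax5+/- cells, and 59 and 51 with centred arrays. Slc1a5 was 8.88-fold lower (-3.15 ± 0.23 (SE), adjusted p = 5.44e-08), and the NK-cell receptor gene Klra8 at least 3.32-fold lower (adjusted p = 0.000495). The ratio of measured Klra8 means was 4.4, and 2.61 without preleukemic wild-type array 1 and 6.7 without array 2. Klra8 and Tmc7 were each at or below the dim level on 6 of 7 Pax5+/- arrays. Edaradd (3.91-fold lower, adjusted p = 9.81e-07), Tmc7 (at least 2.67-fold lower, adjusted p = 1.56e-07) and Klhl14 (3.01-fold lower, adjusted p = 0.000291) also fell. Apobec3, a cytidine deaminase, was 5.89-fold lower (adjusted p = 0.0125), though not without preleukemic wild-type array 3 (adjusted p = 0.142). Ly86 was 3.75-fold higher (1.91 ± 0.29, adjusted p = 0.000872), as in leukemia. Slc1a5, Ly86 and Ccdc12 were the 3 genes called between genotypes at both stages, all in the same direction at each, against 0.197 for independent lists; Ccdc12 was chosen after its values were seen, and Slc1a5 lost its leukemic call without leukemic wild-type array 2 (adjusted p = 0.11). Without preleukemic wild-type array 3, 13 genes were higher and 31 lower, and without preleukemic Pax5+/- array 7, 26 genes were higher.

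Pax5-activated genes did not differ between preleukemic genotypes as a list (median log2 difference -0.07, adjusted p = 0.882), and neither did pro-B and pre-B genes (1 of 24, Enpep, fell by 1.31, adjusted p = 0.67 for the list). The p53 target genes did not pass (adjusted p = 0.0508), except without preleukemic wild-type array 2 (0.0211) or preleukemic Pax5+/- array 1 (0.0377) or 4 (adjusted p = 0.047). DNA replication genes were higher in Pax5+/- cells (2 of 27 adjusted over the list alone, adjusted p = 5.15e-08; adjusted p = 0.835 with an estimated correlation). Their mean was 9.20 in preleukemic wild-type array 1 and 8.29 and 8.43 in arrays 2 and 3, against 8.63 to 9.21 in Pax5+/- arrays, so array 1 did not lie lower. NK-cell genes were lower (adjusted p = 1.33e-06; adjusted p = 0.835 with an estimated correlation), with 1 of 12 lower adjusted over the list alone. Granulocyte genes were lower (adjusted p = 5.18e-06; adjusted p = 0.838 with an estimated correlation), but without preleukemic wild-type array 1 the direction turned (adjusted p = 0.885). Mitosis genes did not pass (adjusted p = 0.162), and without that array they were higher in Pax5+/- cells (adjusted p = 4.07e-14), whereas without wild-type array 2 or 3 they were lower (adjusted p = 5.8e-07 and 1.39e-06).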

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

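The tests with the granulocyte covariate and with the sex of the mice between preleukemic genotypes were chosen only after the results were seen. Leaving out preleukemic wild-type array 1 was planned, but what it would show about that array was written only after the results were seen.

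Leukemic Pax5+/- samples differed from preleukemic ones in 9839 genes. Of 100 splits of these arrays only the real one called as many, the highest other being 6374 in a split that kept all 7 preleukemic arrays together. This makes chance unlikely for the total, although 100 splits cannot exclude it. The granulocyte list, fixed beforehand, was higher in leukemia (adjusted p = 0.007; adjusted p = 0.655 with an estimated correlation), and Ngp and Lcn2, its genes of highest signal, which between probe sets does not rank amounts, went from 8.82 ± 0.70 and 8.47 ± 0.73 (SD, n = 7) to 10.71 ± 1.91 and 10.66 ± 1.93 (SD, n = 10). Of its 20 tested genes 16 lay above the dim level in preleukemic Pax5+/- samples, 0 were in another list, and the labels name no sort. With the granulocyte mean as a covariate 7605 of the calls (77.3%) were kept in the same direction, which argues against granulocyte RNA as the whole cause, while granulocytes may account for part of it, and the difference in cell material between stages stays open.

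Leukemic wild-type samples differed from preleukemic ones in 6115 genes, and of 35 splits only the real 1 called as many (highest other 3752). This makes chance unlikely for the total, but 1 of 35 is the lowest share that 35 splits can reach. Without preleukemic wild-type array 1, 5673 of the calls (92.8%) were kept. On component 1 that array lay nearer the leukemic arrays than the rest of its group did (-17.8, against -50.8 and -56.1). It narrows the stage difference on that component, so leaving it out could hardly remove the calls and decides nothing here. Of the called genes 5 (0.08%) were also called for the Y-linked covariate, which rests on the Pax5+/- arrays and argues against sex as the whole cause. All leukemic wild-type arrays were low and all preleukemic ones high in Y-linked genes, so an effect of sex that appears only in the wild type stays open by design, as does the difference in cell material.

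Preleukemic genotypes differed in 123 genes, and of 100 splits only the real 1 called as many (highest other 38). Chance is thus unlikely for the total, although 100 splits cannot exclude it. With the Y-linked covariate 92 of the calls (74.8%) and without preleukemic wild-type array 1 79 of them (64.2%) were kept, which argues against sex or that array as the whole cause. Called genes lay near each other: 12 pairs stood within 5 tested genes, against a median of 5 and a highest value of 18 in 10000 random sets (one-sided permutation p = 0.0056), among them Slc1a5 with Ap2s1, Tmc7 with Coq7 and Apobec3 with Cbx7. Strain segments that differ between the genotype groups would give such pairs, but neighbouring genes can also share regulation, and the pairs cannot tell these apart. A segment carried with the mutated allele would lie near Pax5. Of 100 neighbours of Pax5 1 was called, against 0.8% of all genes tested, so no excess was seen there. Some pairs shared members, as Zfp428, Irgq and Xrcc1 all paired with one another. A segment would also be present in leukemia, where 3 of the genes were called again, Slc1a5 among them. Apobec3 averaged 11.28 in wild-type and 8.72 in Pax5+/- cells before leukemia, but 9.42 and 9.81 in leukemia. An effect of Pax5 dose on these genes stays open and was not tested.

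The stage change differed between genotypes in 28 genes in 1 direction and 1 gene in the other by the test of the difference itself, and of 100 splits only the real 1 called as many as 29 (highest other 3). Differences were 2.79 for Dock9, 2.26 for Clcf1, 1.95 for Slc1a5, 1.95 for Edaradd, 1.67 for Pacs2, 1.62 for Klhl14, 1.42 for Notch2 and 1.22 for Enpep (log2). Klra8 (2.07, and 1.31 without preleukemic wild-type array 1 or 2.67 without array 2) and Tmc7 (1.55) were called too, but were at or below the dim level on 4 of 4 leukemic wild-type, 6 of 7 preleukemic Pax5+/- and 10 and 9 of 10 leukemic Pax5+/- arrays. Their fitted values therefore mostly restate the difference between preleukemic genotypes and are no exact sizes of a difference in stage change. The same limit holds for Klhl14 and Enpep, which lay near the dim level in leukemia. They averaged 5.34 and 5.35 in leukemic wild-type and 5.38 and 5.26 in leukemic Pax5+/- samples. For Klhl14 the preleukemic genotypes differed by -1.59, close in size to its 1.62. For Edaradd they differed by -1.97, close in size to its 1.95, and its leukemic means were 6.02 in wild-type and 6.01 in Pax5+/- samples. The calls ended without preleukemic wild-type array 3 for Clcf1 (adjusted p = 0.0699), Klhl14 (0.0831), Klra8 (0.0657) and Notch2 (0.0516), and without array 2 for Klhl14 (0.0628). Klra8 also lost its call without leukemic wild-type array 2 (adjusted p = 0.054), 3 (0.0583) or 4 (0.064) or preleukemic Pax5+/- array 5 (0.0509). By list the change was more positive in Pax5+/- mice for pro-B and pre-B (adjusted p = 0.014), pre-B-cell receptor signalling (0.00882), NK-cell (0.0272) and dendritic-cell genes (0.00806). It was more negative for plasma-cell (adjusted p = 0.0221), erythroid (3.1e-08), DNA replication (9.8e-11) and ribosomal protein genes (0.038). None of these 8 lists held with an estimated correlation (adjusted p from 0.627 to 0.774). The pro-B and pre-B call ended without leukemic wild-type array 2 (0.17), the plasma-cell call without leukemic wild-type array 3 (rounded to 0.05, just over the threshold) or preleukemic wild-type array 1 (0.0561), and the dendritic-cell call without the latter (0.761). The NK-cell call ended without leukemic wild-type array 1 (0.0805), 3 (0.219) or 4 (0.23), preleukemic wild-type array 1 (0.6), preleukemic Pax5+/- array 4 (0.0562) or leukemic Pax5+/- array 1 (0.092). The ribosomal protein call ended without leukemic wild-type array 3 (0.104) or 4 (0.0637), preleukemic wild-type array 3 (0.582), preleukemic Pax5+/- array 1 (0.0781), 2 (0.0957) or 3 (0.0981), or leukemic Pax5+/- array 1 (0.0891), 3 (0.0501), 4 (0.0728) or 6 (0.0578).

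Leukemic genotypes differed in 25 genes, and 8 of 100 splits of these arrays called as many or more, with 67 in the highest other split, so chance was not excluded.

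Single arrays stood far from their group in 19 of 129 groups of values of 11 genes and 32 list means, where chance gives about 5%. The preleukemic wild-type group, with 3 arrays, was too small for this test and was not included, and its array 1 had a granulocyte mean of 10.28 against 6.44 and 6.48. Among leukemic wild-type arrays, Pax5 was 6.34 in array 2 (nearest other 10.03) and Myc was 9.97 in array 1 (11.48). The mean of T-cell genes was 7.32 (6.59) and of NK-cell genes 9.46 (6.51) in array 2, and that of monocyte and macrophage genes 7.41 (7.93) in array 4. Among leukemic Pax5+/- arrays, Jak1 was 12.56 in array 7 (10.75), Rag2 8.88 in array 2 (6.84) and Myc 9.09 in array 3 (11.18). In leukemic Pax5+/- array 1 the means were 9.35 for mature B-cell (8.58), 7.69 for NK-cell (6.68), 8.9 for monocyte and macrophage (7.86), 7.5 for non-homologous end-joining (7.75) and 8.65 for NF-kB response genes (7.49). Stromal and endothelial genes averaged 7.05 in leukemic Pax5+/- array 8 (7.69) and DNA replication genes 8.88 in array 7 (9.35). Among preleukemic Pax5+/- arrays, Rag2 was 9.41 in array 3 (9.01), Dntt 9.42 in array 5 (10.29), and the means of NK-cell and dendritic-cell genes were 7.36 (6.44) and 7.23 (6.9) in array 3.

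Probe sets that name no gene also differed between groups. Of 9659 tested, 5742 (59.4%) were called between stages in Pax5+/- mice and 3469 (35.9%) in wild-type mice. The difference of the stage changes called 4, the leukemic genotypes 16 and the preleukemic genotypes 27.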

How the results depend on the processing

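The settings with the Y-linked or granulocyte covariate, with arrays of high or low Y-linked values alone, and the single arrays left out of the overlap and the spread were chosen only after the data were seen. The overlap of calls between genotypes stayed within 1.5 times its counts in every setting run for it. With 1 array left out, named genes stayed on their side of the threshold in 3521 tests, lost the call in 138 and gained it in 5; for gene lists these counts were 2146, 53 and 96, and 9 reversed. Over all settings the sign turned in 50 values of genes that were called in neither setting. Signal near background limits dim genes, and where not stated otherwise the cause was not tested.

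With centred arrays the Pax5+/- stage comparison gave 2827 genes higher and 8930 lower, the wild-type one 5741 lower, the difference between them 6 lower, the leukemic genotypes 27 lower and the preleukemic genotypes 51 lower; centring itself moves all genes of an array. Testing all probe sets, which adds features, gave 10123 and 5759 lower in the stage comparisons of Pax5+/- and wild type, 3 lower for their difference and 32 lower between leukemic genotypes. Quantile normalization again gave 4 lower for the difference, and the mean of a gene's probe sets 3 lower. Arrays with high Y-linked values, a smaller set, gave 2635 lower in the Pax5+/- stage comparison, and 9 higher and 32 lower between preleukemic genotypes. Arrays with low Y-linked values gave 1 higher and 2 lower between leukemic genotypes.

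Between leukemic genotypes trend and robust eBayes gave 5 higher, only the groups compared 1 higher and 0 lower by limma, no filter 11 lower, and the stricter filter 4 higher and 10 lower. The Y-linked covariate gave 3 higher and 0 lower by limma, the granulocyte covariate 5 lower, and the Y-linked covariate without preleukemic wild-type array 1 gave 3 higher and 3 lower. At an unadjusted p < 0.05, of 15647 genes 974 passed with only the groups compared, 1304 with the Y-linked covariate, 792 without leukemic wild-type array 2 and 1189 in the fit of all groups, where chance alone gives 782. For the difference of the stage changes the Y-linked covariate, the granulocyte covariate and the Y-linked covariate without preleukemic wild-type array 1 gave 2, 4 and 8 lower. Between preleukemic genotypes only the groups compared gave 77 higher and 172 lower, and array weights 17 and 43.

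With 1 array left out, counts ran from 2048 to 4066 lower in the wild-type stage comparison, from 10 to 39 higher and 0 to 9 lower for the difference (the 0 by limma without leukemic wild-type array 4, where 447 were lower at an unadjusted p < 0.05), from 1 to 23 higher and 0 to 110 lower between leukemic genotypes, and from 13 to 60 higher and 31 to 93 lower between preleukemic genotypes.

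The replicate numbers did not pair the arrays. After the group means were removed, the median correlation of arrays with the same number was -0.03, 0.03, -0.17 and -0.14 in the comparisons. With the number as a block, the difference gave 14 higher and 3 lower, the leukemic genotypes 1 and 1, the preleukemic genotypes 17 and 39, and Pax5 in the wild-type stage comparison -2.40 (adjusted p = 0.0976).

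The wild-type stage difference of Pax5 passed the limma threshold with all groups in the fit (adjusted p = 0.0256). It did not with only the groups compared (-2.43, adjusted p = 0.115), the Y-linked covariate (-1.85, 0.154), the granulocyte covariate (-1.94, 0.0656), or the Y-linked covariate without preleukemic wild-type array 1 (-2.04, 0.146). With 1 array left out the difference ran from -2.86 to -1.39.

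The median SD of a gene was 0.109 without a filter and 0.156 with the stricter filter in leukemic wild-type arrays, 0.112 and 0.135 in preleukemic Pax5+/- arrays, and 0.131 and 0.204 in leukemic Pax5+/- arrays. With 1 array left out it ran from 0.119 to 0.132 in leukemic and from 0.093 to 0.158 in preleukemic wild-type arrays.

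Hk1 turned from -0.15 to 0.17 in the Pax5+/- stage comparison with the mean of its probe sets. The granulocyte list turned under its own mean as a covariate, which removes it by construction, in the Pax5+/- stage (adjusted p = 0.57), leukemic genotype (0.741) and preleukemic genotype (0.717) comparisons. Without preleukemic wild-type array 1 it turned for the difference (adjusted p = 0.00291, and 0.0419 with the Y-linked covariate) and between preleukemic genotypes (0.885, and 0.961 with the covariate). Between preleukemic genotypes dendritic-cell (0.958), mitosis (4.07e-14, and 2.13e-11 with the covariate) and MYC target genes (0.0354, and 0.00187) turned too. Mitosis genes turned for the difference without preleukemic wild-type array 2 (adjusted p = 0.0164) or 3 (0.036). Without leukemic wild-type array 2, NK-cell (0.119) and interferon genes (2.06e-06) turned between leukemic genotypes. With 1 array left out, the adjusted p ran from 0.00291 to 0.961 (granulocyte) and 7.33e-17 to 0.961 (mitosis) for the difference, and from 0.000347 to 0.119 (NK-cell) and 2.06e-06 to 0.922 (interferon) between leukemic genotypes. Between preleukemic genotypes it ran from 7.01e-12 to 0.885 (granulocyte), 1.4e-05 to 0.958 (dendritic-cell), 4.07e-14 to 0.412 (mitosis) and 0.0271 to 0.969 (MYC target genes).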

Other observations

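The test of Pax5 level against its target genes was chosen before the result was seen.

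Some gene groups differed between preleukemic genotypes beside those described. Plasma-cell genes (adjusted p = 0.0417) and DNA-damage sensing and checkpoint genes (adjusted p = 0.0251) were higher and dendritic-cell genes lower (adjusted p = 0.00461) in Pax5+/- cells, with adjusted p = 0.835, 0.838 and 0.835 with an estimated correlation. The DNA-damage sensing call ended without preleukemic wild-type array 2 (0.689) or 3 (0.557) or preleukemic Pax5+/- array 3 (0.0701) or 6 (0.0577). The plasma-cell call ended without preleukemic wild-type array 1 (0.121) or 3 (0.11) or preleukemic Pax5+/- array 3 (0.0543), 5 (0.0591) or 6 (0.057). Without preleukemic wild-type array 1 the dendritic-cell genes turned in direction (adjusted p = 0.958).

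If the amount of Pax5 set the level of the genes it activates, leukemic Pax5+/- arrays with less Pax5 would have had less of them. Over the 10 arrays Pax5 and the mean of its 23 tested activated genes had Pearson's r = 0.36 (two-sided permutation p = 0.324, adjusted p = 0.648) and Spearman's rho = 0.14 (p = 0.708, adjusted p = 0.708). Without arrays 2 and 1, the farthest from the median of Pax5, r was 0.15 (permutation p = 0.717, n = 8). With 10 arrays the relation could not be told from its absence. The Pax5 probe set may also miss the changed part of the gene, so its signal need not follow functional Pax5.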
